A study of Mus musculus with 16 samples.

How the data were processed

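Gene expression was measured in white and brown adipose tissue of control mice and of mice with an adipose-specific knockout of the glucocorticoid receptor, a ligand-activated transcription factor encoded by Nr3c1. The labels place 16 arrays in 4 groups of 4, and the series' design text calls the 4 of each group biological replicates. Per the labels, total RNA was prepared with a Qiagen RNeasy kit and labelled with Cy3 for 1-colour Agilent arrays. Per the file headers, the scanner images were processed with Agilent Feature Extraction 12.0.0.7, which subtracted the background and removed spatial trends within each array. The deposited scanner files give the intensity of each spot on a linear scale, with no scaling between arrays. The authors' value table holds the mean processed intensity of each probe, also linear and unscaled, because every one of its 41174 probes equalled the mean of the scanner values to within rounding on all 16 arrays; its direction and scale are therefore known.

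Each array carried 43379 spots that were not controls, and between 67.3% and 77.0% of them were well above background. No spot was saturated. The number of arrays limits the precision. Spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged. The main values were log2 processed intensity minus the 75th percentile of each array. Probes were named by matching their RefSeq accession to a table of the GRCm38.p6 assembly. This matched 28223 of the 41174 probes to 19096 gene symbols, and 12951 probes stayed unnamed and were kept out of the gene tests. The array design names another assembly, so no coordinates are given. A probe was kept if it was well above background on all 4 arrays of at least 1 group, and each gene was represented by its brightest kept probe, which left 15468 genes. Of the unnamed probes, 6604 passed this filter and were tested apart. In white knockout 0 of them were called and in brown knockout 1, with 208 between tissues of controls and 46 of knockouts.

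The arrays of each group were compared before averaging, over probes above the 75th percentile and well above background on all 16 arrays. Differences between arrays were divided by the error that Feature Extraction assigns to each spot, and arrays of a group were taken as 1 sample where the median absolute deviation of this ratio was below 1. The 16 arrays then formed 9 distinct samples, which were averaged and counted once each: 2 white control, 2 white knockout, 3 brown control and 2 brown knockout samples. This choice was made after seeing the data, and it departs from the planned fit to 16 separate arrays, which is given as an alternative. On simulated data the rule recovered the 9 samples when array noise was 0.25, 0.5 or 0.75 of the stated error. At a noise of 1 times the error it found 12. It also merged simulated animals that differed by an SD of only 0.1 on the log2 scale when array noise was 0.5 of the error or less, so animals that similar would not have been told from repeat arrays. Pooled RNA would look the same as a single animal's RNA. Simulated array noise was a share of the error that the ratio divides by, which fixed the ratio of simulated repeats near that share. Recovery of the 9 samples therefore does not show that the real arrays are repeats.

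Groups were compared with limma 3.58.1 in R 4.3.3, in a model with a mean for each of the 4 groups and 1 pooled spread per gene, with 5 residual degrees of freedom. The contrasts were knockout against control in each tissue, the difference between those effects, and brown against white in each genotype. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. With 2 samples in a group, p-values rest on the pooled spread. Gene lists were tested with camera at a preset correlation of 0.01, over 27 of 28 lists fixed before the data were examined; the list of epididymis and male duct genes had fewer than 5 tested members. Camera with an estimated correlation and fry were alternatives. A gene not well above background on any array of a group has only a bound there. It is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of its own signal and the lowest signal among probes well above background.

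The rule for naming genes was also fixed before the data were examined. In the knockout comparisons it took Nr3c1, the 12 largest rises and 12 largest falls among genes past the threshold whose 4 knockout arrays all lay beyond the 4 control arrays, or the 5 genes with the smallest p where none passed, leaving out names that are not gene symbols. In the comparison of tissues it took the 10 largest differences each way. From each list it took up to 4 members past the threshold or up to 2 with the smallest p, and any glucocorticoid-induced gene. Where none passed, the genes that the rule takes from the 16-array fit are named too, as such.

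The fit was tested on simulated data with the spreads of these samples. For white knockout against control, 200 of 15448 genes were changed, 50 at each size. The fit recovered 1.8% of genes changed 2-fold, 46.4% of those changed 4-fold and 80.4% of those changed 16-fold. These rates hold for that share of changed genes. It called 0 genes when none was changed. With no gene changed, the 16-array fit called a median of 1462 genes, because simulated repeat arrays of a sample were counted as separate animals. The simulation built the arrays as repeats of 9 samples, so this excess was fixed in advance. It does not show that the real arrays are repeats. Camera called a planted list in 10 of 10 runs and 1 of 260 random lists. In this simulation the genes varied independently of each other. The estimated correlation within the real lists ranged from -0.046 (mast cells, eosinophils and neutrophils) to 0.94 (proliferation). The rate for random lists therefore says nothing about false calls of lists whose genes vary together.

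Same-numbered arrays were checked for pairing. Between white and brown knockout arrays the deviations from the group means correlated at 0.570, 0.436, 0.471 and 0.294 for numbers 1 to 4, across genes. Arrays 2, 3 and 4 are 1 sample in each tissue, so the 4 values reflect 1 contrast between 2 samples. The pairing comes from the data: number 1 stood apart from numbers 2, 3 and 4 in both tissues. The blocked counts stand beside the tissue comparison in knockouts and the difference between knockout effects. Numbers did not pair the other groups. Control and knockout arrays of 1 tissue, which come from different mice, still correlated at -0.538 to 0.412. Values of about this size therefore do not show a shared mouse. Alternatives covered the scaling, background correction, filter, probe choice, samples in the fit, moderation, array weights, slide, replicate number, thresholds and each array or sample left out. The background alternative (normexp, offset 50) used the median spot intensity, because the scanner files analysed here hold no mean intensity column. Slide and scan batch coincided, with 5 of each. The figures were drawn with matplotlib 3.10.9.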

Results

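The study asked what loss of the glucocorticoid receptor in adipose tissue does to gene expression in white and brown fat. Each of the 4 groups, white control, white knockout, brown control and brown knockout, was measured on 4 arrays. Between 67.3% and 77.0% of the spots of an array were well above background. Of the 24 pairs of arrays within a group, 9 differed by less than the scanner's own error, with ratios of difference to error between 0.375 and 0.653, and had at most 12 of 9754 bright probes more than 2-fold apart. The other 15 pairs had ratios of 1.09 to 4.24 and at least 260 such probes. Arrays that differed by less than this error were averaged and counted as 1 sample, a choice made after seeing the data: white control 1 and 4, white control 2 and 3, white knockout 2, 3 and 4, brown control 2 and 3, and brown knockout 2, 3 and 4. The tests therefore compare 2 white control with 2 white knockout samples, and 3 brown control with 2 brown knockout samples.

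**Figure D1:**
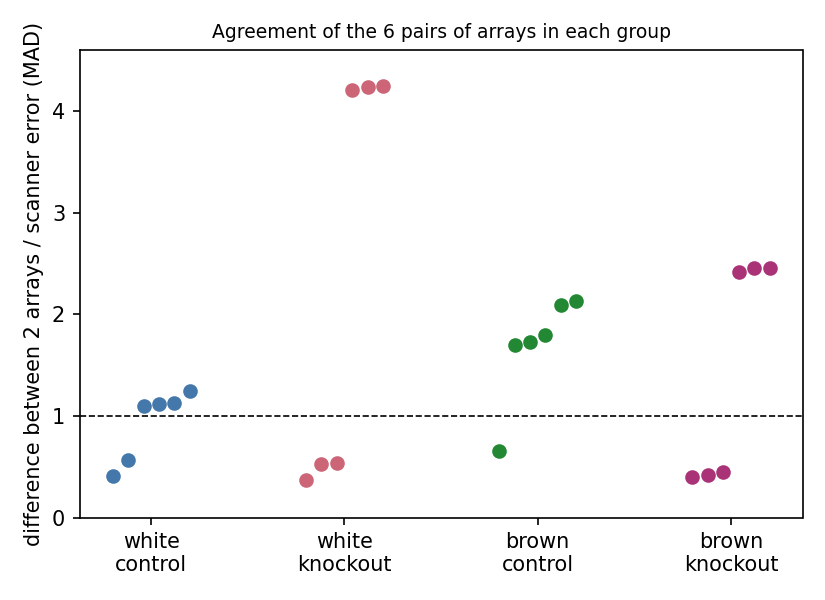
Ratio of the difference between 2 arrays of a group to the scanner software's error (vertical axis, median absolute deviation over bright probes), with 1 point for each of the 6 pairs in each of the 4 groups; the dashed line is the limit of 1. The 9 pairs below the line reach 0.653 at most, and the 15 above it start at 1.09.

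Nr3c1, the targeted gene, was lower in knockout samples of both tissues. Its brightest probe lay between 2.01 and 2.43 on white control arrays and between 1.23 and 1.5 on white knockout arrays, as log2 relative to the 75th percentile. In brown fat the ranges were 2.29 to 2.63 and 1.5 to 1.76, so every knockout array lay below every control array. The differences were -0.90 ± 0.23 (SE) in white and -0.85 ± 0.21 in brown fat, or 46.2% and 44.7% less signal. With the authors' unscaled values, where the median of all brown knockout effects was 0.31, the brown difference was -0.42. Neither passed the limma test over all genes (adjusted p = 0.413 and 0.620), although both did when all 16 arrays were counted as separate samples (adjusted p = 0.000195 and 0.00339). On the 9 samples the unadjusted limma p of this probe was 0.0055 in white and 0.0044 in brown fat. For the other 3 probes it ranged from 0.0023 to 0.41 in white and from 0.0070 to 0.19 in brown fat. The other 3 probes of the gene were also lower on average in both tissues, by between 15.2% and 53.6% in white fat and between 21.5% and 43.1% in brown fat. The labels do not say which exon was deleted, and the positions of the probes relative to it are not known.

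**Figure D2:**
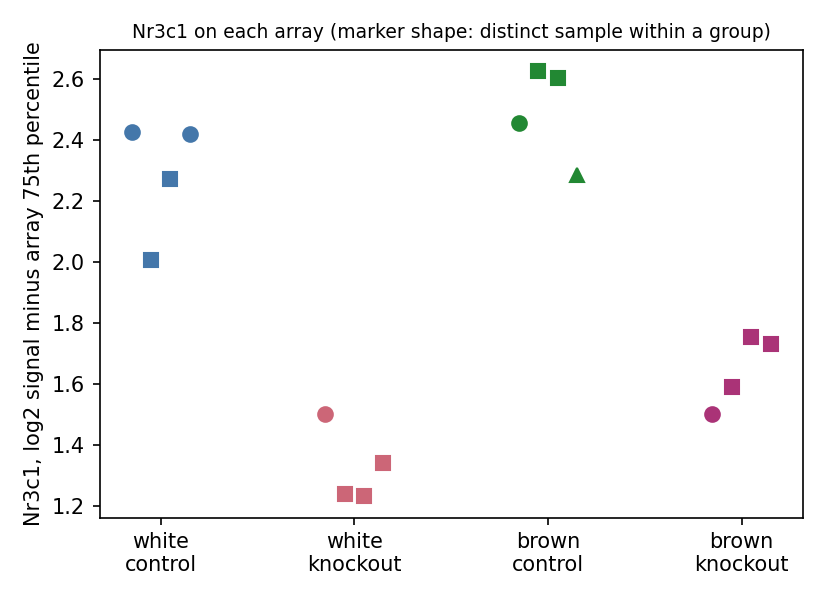
Log2 Nr3c1 signal relative to each array's 75th percentile (vertical axis) on the 16 arrays, by group; points of 1 shape within a group are arrays of the same distinct sample. White knockout arrays lie between 1.23 and 1.5 and brown knockout arrays between 1.5 and 1.76, below the lowest control array of their tissue (2.01 and 2.29).

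In white fat, gene groups of lipid synthesis were lower in the knockout. All 20 measured genes of de novo fatty acid synthesis had lower means, with a median log2 change of -1.68, and this held in both knockout samples (-1.67 and -1.77 against the control mean). Mlxipl, a carbohydrate-sensing transcription factor that drives lipogenic genes, was at -1.64 ± 0.32 (SE), and Pnpla3 at -1.67 ± 0.36. Cholesterol synthesis genes were lower in 17 of 20 members (median -1.16; -1.17 and -1.13 in the 2 samples), with Sc5d, a late enzyme of the pathway, at -1.67 ± 0.29. Camera placed both lists below other genes (adjusted p = 1.16e-11 and 7.84e-07), but neither call held with an estimated correlation (adjusted p = 0.536 for each). No member of either list passed over all genes tested, while 14 and 11 passed adjusted over the list alone.

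Other adipocyte groups were much lower in 1 of the 2 white knockout samples, the one measured on arrays 2, 3 and 4, than in the other. T, B and NK cell markers were at 2.88 in that sample and -0.74 in the other. The list of adipocyte identity and adipokines had a median change of -0.90 and lower means in 21 of 21 genes, yet its median was -1.79 in that sample and -0.041 in the other. Retn, the adipokine resistin, was at -2.39 ± 0.39 (SE), and Mest, an imprinted gene linked to fat expansion, at -3.15 ± 0.61. Lipolysis genes (median -0.92; G0s2, an inhibitor of lipolysis, at -1.69 ± 0.41), triglyceride synthesis genes (-1.06; Mogat2 at -1.95 ± 0.27), fatty acid oxidation genes (-0.84; Decr1 at -1.26 ± 0.56), extracellular matrix genes (-0.99; Lox, which cross-links collagen, at -1.60 ± 0.48) and progenitor markers (-1.15; Ccn5 at -1.91 ± 0.53) were alike, with medians between -1.83 and -1.47 in that sample and between -0.34 and -0.16 in the other. Camera called these 6 lists lower (adjusted p from 3.09e-06 to 0.00152) and none held with an estimated correlation (adjusted p = 0.536 to 0.635). The adipocyte list passed in 4 members adjusted over the list alone and in 0 over all genes.

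Markers of other cells differed between the 2 white knockout samples. T, B and NK cell markers were higher in white knockout, in 21 of 23 members, with a median of 1.10, though the 2 white control samples also differed (-0.90 and 0.90). Jchain, the joining chain of secreted antibodies, was at 1.83 ± 0.75 (SE). Proliferation genes had a median of 0.96 (2.49 and -0.54; Ccnb1, a mitotic cyclin, at 2.02 ± 1.20), and skeletal muscle genes a median of 0.57 (1.40 and -0.14). Mesothelial markers, from the lining of the abdominal cavity, had a median of -1.41 (-3.0 and 0.17), erythroid genes one of -1.49 (-2.52 and -0.68), endothelial markers -0.67 (-0.89 and -0.10) and respiratory chain subunits -0.39 (-0.63 and -0.14). Interferon-stimulated genes (median -0.73; -0.65 and -0.82) and acute phase genes (-0.63; -0.87 and -0.65) were lower in both knockout samples, and the interferon list lay at -0.48 and 0.48 in the controls. Camera called 17 of 27 lists in white fat, 3 higher and 14 lower, and 0 with an estimated correlation (lowest adjusted p = 0.536) or with fry (lowest 0.147). Without the 3-array knockout samples of both tissues, camera called the T, B and NK list lower in white fat (-0.74) and the proliferation list too (-0.54). The lists not called in white fat had medians of -0.58 for insulin signalling, -0.33 for adrenal steroid metabolism, -0.15 for the circadian clock, 0.42 for cytokines, -0.19 for immediate early genes, -0.22 for mast cells, eosinophils and neutrophils, -0.22 for Schwann cells and -0.13 for thermogenic genes. Macrophage markers had a median of 0.049 with a mean and test direction below 0, but lay at 0.74 in the sample on arrays 2, 3 and 4 and at -0.77 in the other. Hsd11b1, which regenerates active glucocorticoid, was at -2.19 ± 0.51 in white and -1.40 ± 0.46 in brown fat.

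No single gene passed in white fat: limma called 0 of 15468 genes, with 1546 at an unadjusted p below 0.05 against 773.4 by chance. The 5 with the smallest p were Pdzk1ip1 (-2.41 ± 0.23 SE), Cpne4 (5.25 ± 0.52, at least 12.2-fold), the glutathione transferase Gsta1 (-3.86 ± 0.40), Speer6-ps1 (3.95 ± 0.46, at least 5.37-fold) and the intestinal lactase gene Lct (3.13 ± 0.38), with a lowest adjusted p of 0.135. Counting 16 arrays as separate samples called 6904 genes, 2938 higher and 3966 lower. In that fit the rule named, among the largest rises, Coch, Nsg2, Grem1, Nefh, Cacna1b, Syt13, Astn1, Cemip, Grpr and Cdc25c, with Grem1, a secreted BMP antagonist, at 4.07. The largest falls there included Tex19.1, Acsm3, Gsta3, Cyp2f2, Alb, Capn6, Timp4, Syce1, Chst13 and Folh1, with Gsta3 at -4.12. The averaged fit gave Grem1 4.57 ± 1.28 and Gsta3 -3.78 ± 0.46, neither past the threshold. Leaving out white knockout array 1, which leaves 1 knockout sample, gave 1658 genes, and leaving out arrays 2, 3 and 4 gave 116.

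**Figure D3:**
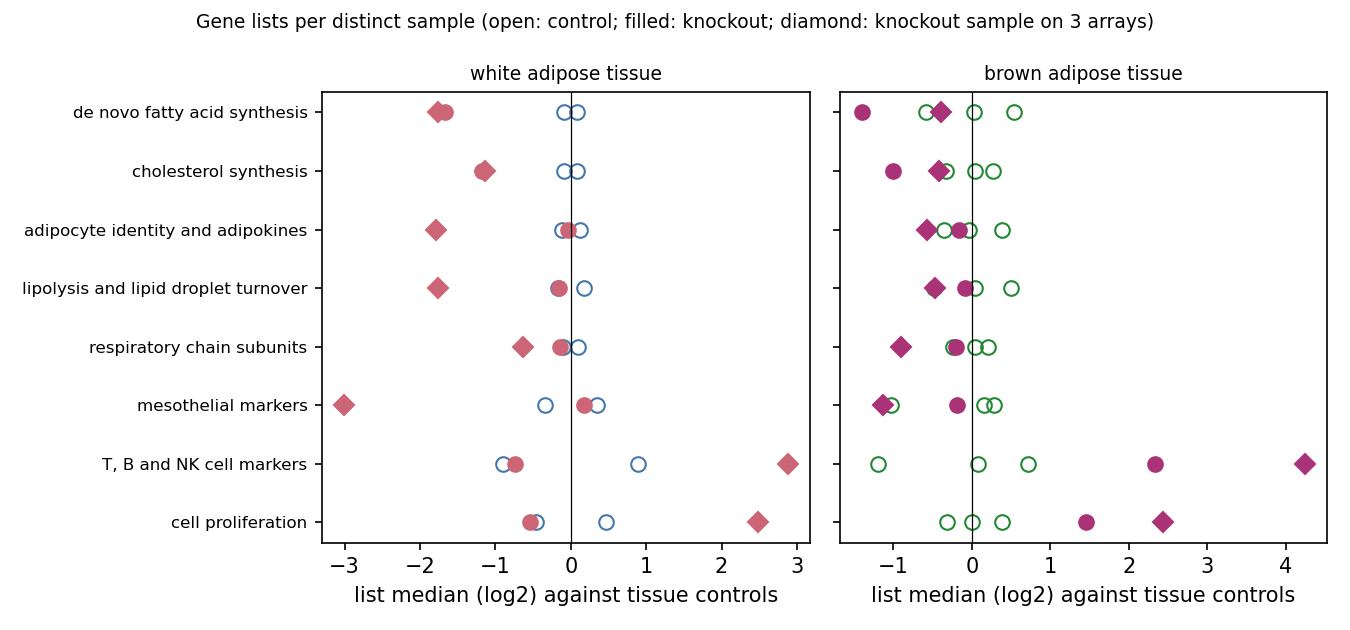
Median log2 level of 8 gene lists in each distinct sample, relative to the mean of the tissue's control samples (horizontal axis), in white and brown fat; open circles are controls, filled circles and diamonds knockouts, and diamonds the samples measured on 3 arrays. Fatty acid synthesis is low in both white knockout samples (-1.67 and -1.77), whereas the adipocyte list is low in the 3-array sample (-1.79 against -0.041).

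In brown fat, lymphocyte markers stood out. T, B and NK cell markers had a median change of 3.22, at 2.34 in knockout sample 1 and 4.25 in the sample on arrays 2, 3 and 4, with Il7r, a lymphocyte cytokine receptor, at 5.47 ± 1.22 (SE) and Jchain at 2.60 ± 0.68. Proliferation genes had a median of 1.91 (1.46 and 2.44; the mitotic kinase gene Cdk1 at 2.45 ± 0.92). All 57 respiratory chain subunits had lower means, with a median of -0.55 (-0.20 and -0.90; Atp5a1 at -0.65 ± 0.24). The control samples ranged from -0.24 to 0.21, so knockout sample 1 lay within them. The 3-array sample also had lower skeletal muscle genes (-1.44). Transcripts of muscle and of brown fat cells cannot be told apart in bulk tissue, so this fall is not assigned to brown adipocytes. Fatty acid synthesis genes were lower in 20 of 20 members (median -0.96; -1.40 and -0.39), where the control samples ranged from -0.58 to 0.53, and cholesterol synthesis genes in 17 of 20 (median -0.79; Fdft1 at -0.93 ± 0.27). Skeletal muscle genes were lower in 26 of 26 (median -0.82; Actn3 at -1.25 ± 0.37), at -0.34 in knockout sample 1 and -1.44 in the 3-array sample, where the lowest control sample was at -0.28. Camera called 12 of 27 lists, 2 higher and 10 lower, and 0 with an estimated correlation (lowest adjusted p = 0.723) or with fry (lowest 0.383). The remaining lower lists were extracellular matrix (-0.66), acute phase (-0.52), endothelial (-0.42), adipocyte identity (-0.35; -0.16 in knockout sample 1, within the controls), triglyceride synthesis (-0.50) and erythroid genes (-0.85). With the authors' unscaled values, where the median of all genes was 0.31, the adipocyte and endothelial medians were above 0. The uncalled lists included lipolysis (-0.28), fatty acid oxidation (-0.45), insulin signalling (-0.29), adrenal steroid metabolism (-0.25), clock genes (-0.24), interferon-stimulated genes (-0.30), progenitor markers (-0.61), immediate early genes (-0.26), granulocyte and mast cell markers (-0.67) and mesothelial markers (-0.39). Cytokine, macrophage and Schwann cell medians lay between -0.0058 and -0.0011, with a test direction above 0. Leaving out brown knockout array 1 left 7 lists called. Thermogenic genes were not called (median -0.40, adjusted p = 0.518 by camera; Cox7a1 at -0.67 ± 0.47).

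In brown fat limma called 0 of 15468 genes, with 1090 at an unadjusted p below 0.05 against 773.4 by chance. The smallest p belonged to Gsta3 (-4.07 ± 0.42 SE), Spef2 (2.01 ± 0.26, at least 1.55-fold), Speer6-ps1 (2.89 ± 0.42, at least 2.13-fold), Spn-ps (-1.25 ± 0.18) and Gsta1 (-2.37 ± 0.37), with a lowest adjusted p of 0.395. Spef2 and Speer6-ps1, both dim in controls, were lower rather than higher with the normexp background. The 16-array fit called 4720 genes, 1960 higher and 2760 lower. Its largest rises included Lef1, Il7r, Ccr7, Cd8a, Tcf7 and Lck, which T lymphocytes express, with Lef1 at 6.45 in that fit and 6.09 ± 1.88 in the averaged fit, besides Nsg2, Dapl1, Afp and Tspan10. Its largest falls were Gsta3, Mug1, Serpina3k, Cyp2c40, Kera, Alb, Uox, Smco1, Msln, Gsta1, Mmp13 and Cyp2f2.

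Genes that glucocorticoids are known to induce were not called as a list in either tissue. Of 29 measured, 17 had lower means in white knockout and 16 in brown (medians -0.21 and -0.10, camera adjusted p = 0.768 and 0.912). The brown median and its test differed in sign, and it was above 0 with the authors' values and with normexp. None passed over all genes; adjusted over the list alone, 2 passed in white and 1 in brown fat. The sulfotransferase gene Sult1a1 was at -1.98 ± 0.30 (SE) in white and -1.35 ± 0.27 in brown, and the phosphatase gene Dusp1 at -1.28 ± 0.24 and -0.53 ± 0.22. Fkbp5, a chaperone of steroid receptors that glucocorticoids raise, was at 1.74 ± 1.04 and 1.79 ± 0.95, and Tsc22d3 at 0.78 ± 0.36 and 0.054 ± 0.33.

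The knockout effects of the 2 tissues, which share no array, correlated at r = 0.537 (Spearman's rho 0.547) over 15448 genes, which are not independent replicates, and had the same sign in 72.8%. No gene was called in both. Within 1 tissue, knockout and control arrays did not overlap for 29.4% of genes in white fat and 28.0% in brown fat. Chance, reckoned for samples rather than arrays, is 33.3% and 20%. In one direction in both tissues the arrays did not overlap for 9.70% of genes. Chance, again for samples, gives 3.33% only if the tissues vary independently. Same-numbered knockout arrays deviated together (r from 0.294 to 0.570), though arrays 2, 3 and 4 are 1 sample in each tissue. The share is therefore not a test of shared change. Examples chosen after their values were seen are Gsta3, Cyp2f2 and Alb, lower in both, and Nefh, higher in both (3.81 in white, 3.79 in brown). Without the white knockout sample on arrays 2, 3 and 4, r was -0.029; it was 0.14 without the 3-array samples of both tissues, 0.26 with the lymphocyte score as a covariate and 0.36 without white control arrays 1 and 4.

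No gene's knockout effect differed between tissues by limma, and none did with the knockout samples paired by number. At an unadjusted p below 0.05 limma found 403 genes, fewer than the 773.4 expected by chance. The smallest p belonged to Camk2a (-3.24 ± 0.52 SE, brown minus white), Cdh24 (-2.88 ± 0.50), Adgrb3 (-3.60 ± 0.65), Lingo2 (-4.13 ± 0.81) and Pdzk1ip1 (1.61 ± 0.32), with a lowest adjusted p of 1. Counting 16 arrays as separate samples called 618.

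Brown and white fat of control mice differed clearly. Limma called 780 genes, 606 higher and 174 lower in brown. Muscle genes led: 25 of 26 skeletal muscle genes passed, with a median of 9.79, among them the calcium buffer gene Pvalb (13.63 ± 1.18 SE, adjusted p = 0.00122), Tnnt3 (12.15 ± 0.89) and Myh7 (11.98 ± 1.23). Ckmt2, a mitochondrial creatine kinase gene of muscle and brown fat, was at 15.28 ± 1.11, of which at least 9613-fold can be read, because white fat was not above background. Xirp2 and Myom2 were also among the 10 largest estimates, as were Myot, Csrp3, Mybpc1, Fitm1 and Smtnl1, for which only a bound can be read, so these genes are not ranked. Thermogenic genes rose in brown fat as a list (median 1.73), with Cox7a1 at 5.98 ± 0.47 and Cox8b at 3.50 ± 0.46, as did respiratory chain subunits (57 of 57 higher, 10 passed, median 1.21). With an estimated correlation the adjusted p was 0.522 for each of these lists. Skeletal muscle genes lay at median levels of 6.92 to 7.79 in the brown control samples. Transcripts of muscle and of brown fat cells cannot be told apart in bulk tissue, so neither rise is assigned to brown adipocytes. The muscle, respiratory chain, acute phase, endothelial and granulocyte and mast cell lists passed fry. Camera called 15 of 27 lists, 5 higher and 10 lower, and 0 with an estimated correlation; the lowest adjusted p with an estimated correlation was 0.0588.

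White fat of controls held more of several mesothelial markers: 9 of 14 were lower in brown and 5 passed (median -3.94), while 5 had higher means, and camera's adjusted p was 0.00276, or 0.698 with an estimated correlation. Upk3b (-8.37 ± 1.32 SE), Wt1 (-7.57 ± 0.99, at least 84.3-fold), Upk1b (-7.04 ± 1.17, at least 60.5-fold) and Msln (-5.61 ± 1.06) fell in brown against white, as did the transcription factor genes Tcf21 and Nkx2-3, the retinoic acid synthesis gene Aldh1a2, and Nkain4, Crb2 and Gabra4. Macrophage markers were lower in brown fat in 27 of 27 members (median -1.12), with Trem2 (-2.34 ± 0.50) and Lyve1 (-2.30 ± 0.44) past the threshold, as were the endothelial genes Plvap (-1.67 ± 0.25) and Pecam1 (-1.05 ± 0.21). With the authors' unscaled values, 935 genes were called and 51.1% were higher in brown, against 77.7% with the main scaling. Leaving out white control arrays 2 and 3 left 178 genes, white control arrays 1 and 4 left 182, brown control array 1 left 342, arrays 2 and 3 left 313 and array 4 left 478. Leaving out one or the other white knockout sample gave 1741.

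In knockout mice limma called 238 genes between the tissues, 204 higher and 34 lower in brown. With the knockout samples paired by number, a pairing read from the data, the count was 625, 463 higher and 162 lower, including all 238. Leaving out brown knockout array 1 left 112, either white control sample 143, white knockout array 1 368 and white knockout arrays 2, 3 and 4 1010, and fitting these groups alone called 0.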

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

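The tests of dilution, repeat arrays and sex-linked genes were chosen only after the results were seen. The knockout effect differed between tissues, brown minus white, for 11 lists by camera's test of the difference. The median differences were 0.71 for lipolysis, 0.73 for fatty acid synthesis, 0.66 for triglyceride synthesis, 0.68 for adipocyte identity, 0.38 for cholesterol synthesis, 0.38 for interferon-stimulated genes, 0.50 for progenitor markers, 0.71 for proliferation, 1.94 for T, B and NK cells, -1.42 for skeletal muscle and 1.03 for mesothelial markers. Most depended on 1 white knockout sample. Without the one on 3 arrays, lipolysis (-0.13), triglyceride synthesis (-0.047), adipocyte identity (-0.20), progenitor (-0.20) and mesothelial markers (-0.74) no longer passed and were below 0. Without the other, proliferation turned to -0.70, and T, B and NK cells (0.30), cholesterol synthesis (0.34) and interferon-stimulated genes (0.27) no longer passed. None held with an estimated correlation (adjusted p = 0.733 for each of them), and with the authors' values 3 lists differed. Only white samples were left out above. Without one or the other, fatty acid synthesis (0.64 and 0.75) and skeletal muscle (-0.70 and -2.23) kept their direction. Their brown values also differed by sample. Fatty acid synthesis was at -1.40 in brown knockout sample 1 and -0.39 in the 3-array sample, against -1.67 and -1.77 in white fat. Skeletal muscle was at -0.34 and -1.44 in brown fat, against -0.14 and 1.40 in white.

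Lower adipocyte and lipid synthesis genes may reflect lymphoid tissue in the knockout samples, such as a lymph node taken with the fat, which would dilute all adipocyte RNA alike. For adipocyte identity the fit without the samples on 3 arrays cannot decide this. Its medians there were -0.041 in white fat and -0.162 in brown fat, as dilution would give. However, only knockout sample 1 is left, and leaving out the low sample removes the fall whatever its cause. In brown fat lymphocyte markers were still at 2.34 in that sample. The 3-array samples had lymphocyte marker levels of 1.90 in white and 1.89 in brown fat, with adipocyte identity at -1.79 and -0.57. For fatty acid synthesis the values in knockout sample 1 argue against dilution as the whole cause. In that sample the list's median minus that of adipocyte identity was -1.63 in white fat (spread 0.39) and -1.24 in brown fat (spread 0.37). Control samples lay between -0.23 and 0.15. The white and brown sample 1 may come from 1 mouse, and the spread treats the genes of a list as independent. This comparison replaced an earlier one, which could not decide, after the values per sample had been seen. In brown fat the 3-array sample had more lymphocyte marker (4.25) but fatty acid synthesis at -0.39, within the controls, while knockout sample 1 was at -1.40. Dilution stays open as a part, since the 2 lists lay together in the 3-array samples (0.024 and 0.18), and so does an effect of the receptor, which was not tested apart from other differences between the samples.

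Arrays that agreed closely within a group were tested again over 14213 dimmer probes that had not been used to form the samples. The highest ratio of difference to error among the 9 agreeing pairs was 1.02 there, for brown control 2 and 3, above the limit of 1. The lowest among the other pairs was 1.42. Between 178 and 543 of these probes were more than 2-fold apart in agreeing pairs, and at least 655 in the others. The gap between the pairs thus recurred. These probes come from the same arrays, and pairs picked as closest over bright probes tend to stay close, so separate animals were not tested independently. The 7 agreeing pairs on different slides had a median ratio of 0.84, as 1 RNA sample or pool on several arrays would give. Animals that differ very little stay open too, as does a pool, and no biological explanation was tested.

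The labels call all mice male, whereas Xist, the transcript of the inactive X chromosome, was well above background by 4 of 4 probes on all 16 arrays, which argues against 1 probe reading another transcript. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty, Zfy1) were well above background on 1 array, at 1 of 7 probes. This is consistent with female tissue. No array of known male tissue was analysed here to show that the Y-linked probes work.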

How the results depend on the processing

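The fit first planned counted all 16 arrays as separate samples, and averaging them to 9 samples was chosen after seeing the data. Also chosen then were the fit without the 3-array samples, the lymphoid covariate, the pairing of distinct knockout samples and leaving out whole samples. Signal over background limits dim genes, and the 2 or 3 samples a group limit the rest. What counts as a sample changed the gene counts most, and the correlation assumed within a list the list counts. With 16 separate arrays the counts were 6904 (white knockout), 4720 (brown knockout), 618 (difference between tissues), 6075 (tissues, controls) and 3965 (tissues, knockouts), with 2356 genes shared in direction between the knockout effects, 7 lists in brown fat, and Nr3c1 at -0.95 in white and -0.85 in brown past the threshold. With slide as a random block on those arrays they were 6952, 4728, 677, 6129 and 4022, with 2368 shared and Nr3c1 at -0.95 and -0.85. With the replicate block on those arrays they were 7101, 4960, 696, 7511 and 5216, with 2650 shared, 7 lists in brown fat and Nr3c1 at -0.95 and -0.85; pairing the distinct knockout samples instead gave 625 for the tissues of knockouts, and 0 genes and 11 lists for the difference. In simulated data with no change, built as repeats of the 9 samples, counting arrays as separate samples called a median of 1462 genes. That excess was fixed by the design of the simulation, so it does not show that the calls on the real arrays are false. On the 9 samples, no scaling, filter, probe rule, trend or threshold called a gene in either knockout comparison, except 1 gene in brown fat when only its groups were fitted. That fit gave 2340 and 0 genes between tissues in controls and knockouts, array weights 4610 and 80, the filter on all arrays 493 and 104, and an adjusted p of 0.1 gave 1489 and 467. Slide as a fixed block gave 1215 in controls. Without both 3-array samples 148 genes were called in white fat, 2340 and 912 between tissues, and 3 lists differed between tissues; with the lymphoid covariate the tissue counts were 1234 and 656. An estimated correlation called 0 lists in all 4 comparisons, and fry 0, 0, 0 and 5. Normexp gave 6 lists in brown fat and 21 for the difference, and the authors' values 3. Over arrays and samples left out, genes called ranged from 0 to 1658 in white knockout (116 without knockout 2, 3 and 4), 0 to 1 in brown knockout, 0 to 48 for the difference, 178 to 1741 between tissues of controls (342 without brown control 1, 478 without 4, 313 without 2 and 3, 182 without white control 1 and 4), 112 to 1010 in knockouts (143 without either white control sample, 368 without white knockout 1), and 0 to 1 shared. Lists ranged from 9 to 18 in white, 7 to 15 in brown (13 at most for single arrays), 8 to 14 for the difference and 14 to 18 between tissues, and Nr3c1 from -1.04 to -0.75 in white and -0.95 to -0.76 in brown. Each leaves fewer samples; where a group keeps 1 sample, it is assumed to vary like the others. No further cause was tested. The median of all genes moved most with the authors' values, to -0.23 in white and 0.31 in brown, 0.64 for the difference, and -0.43 and 0.25 between tissues.

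Some lists changed direction. The difference of respiratory chain effects was 0.034 with normexp and 0.19 with the lymphoid covariate (-0.51 to 0.22 with samples left out), and that of proliferation ranged from -0.70 to 1.12 with single arrays left out and to 2.24 with whole samples. Without both 3-array samples, white fat gave -0.61 for cytokines, -0.54 for proliferation, -0.74 for T, B and NK cells and 0.54 for Schwann cell genes, and brown fat -0.62 for cytokines and -0.46 for macrophage markers. With samples left out, the white medians ranged from -0.61 to 1.02 for cytokines and from -0.54 to 2.49 for proliferation, the brown macrophage median from -0.46 to 0.38, and the correlation of knockout effects from -0.029 to 0.67. With the lymphoid covariate, brown fat gave 0.66 for lipolysis, 0.47 for fatty acid oxidation, -0.94 for cytokines, -0.79 for macrophage markers and 1.24 for mesothelial markers. The cause was not tested. The slides that hold both groups gave 0 genes in each knockout comparison and for the difference. Camera takes no random block, so slide as a random block was not run for lists, and no slide holds both tissues of 1 genotype.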

Other observations

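The test of gene neighbours and its bounds were chosen before its result was seen, and the counting spread of 4.36 after. Genes whose knockout and control arrays did not overlap, in one direction in both tissues, could lie on strain segments carried along with the deleted allele. Among the 100 such genes with the largest smaller difference, none of which passed the test in either tissue, 9 neighbours lay within 5 tested genes of each other, against a median of 3 and a 95th percentile of 6 in 10000 random sets. The 100 genes that differed most between tissues gave 10, so the bound of not exceeding these was met, but within the counting spread, and strain segments can neither be excluded nor told from other causes of closeness. The neighbours included Orm1 with Orm3, Orm3 with Orm2, Serpina3k with Serpina3n, Mest with Klf14, Slc15a2 with Eaf2, Aldh1a1 with E030003E18Rik, Ada with Ccn5, and Nt5e with Zfp949.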
